A study of Mus musculus with 16 samples.

How the data were processed

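Poly(A) RNA was measured in mouse bone-marrow B-lineage cells that had been enriched for B220, transduced in culture with a Hoxb5 virus or a GFP control virus and sorted as transduced pro/pre-B cells, 1000 cells per library. There were 8 control and 8 Hoxb5 libraries. Per the labels' protocols, cDNA was amplified from few cells, checked by the genes B2m, Actb, Gapdh and 1 more read here as Eef1a1, made into libraries with a transposase kit and sequenced on a NextSeq.

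The deposited table holds FPKM values, which the authors made with bcl2fastq, TopHat, Cufflinks 2.2.1 and Cuffnorm on the mm10 genome, per the submitters' processing notes. FPKM values are corrected for transcript length and library size, hold no counts, and the labels state neither strand use nor how reads that fit several genes were shared. Reads of overlapping genes and close paralogs, such as the Klra family, the H2 genes and the Vpreb genes, are therefore uncertain between members. Gene names, positions, GC content and lengths came from GENCODE M21 by gene identifier: 32916 of 37980 genes had a symbol, 5064 did not, 6 symbols were shared by several identifiers, and 18638 genes were at 0 in every library.

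Depth in reads was not analysed here. A relative depth was read from the commonest ratio of low values between libraries, with GFP control 1 set at 1: controls ran from 0.825 to 1.41 and Hoxb5 libraries from 1.44 to 1.61, except Hoxb5 8 at 1.00. Genes near 1 FPKM are measured with less precision than genes at 10 or more.

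The comparison, tests, filter, gene lists and naming rule were set before the data were examined. Genes with at least 1 FPKM in at least 4 of 16 libraries were kept (11694, of which 11129 had a symbol), transformed as log2(FPKM + 1) and tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend), with p-values adjusted by Benjamini and Hochberg at 0.05. Fixed lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, with p-values adjusted over the 17 lists tested. Members were also adjusted over the list alone. Library-level values and list means were compared by exact permutation over 12870 regroupings, where the smallest p is 0.000155. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9.

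The genes named were Hoxb5, the 4 genes of the cDNA check, the 12 called genes with a symbol with the largest difference in each direction that lay on the same side of the control median in at least 7 of 8 libraries, and up to 4 called members of each fixed list with the smallest p, or 2 tested ones where none was called. Genes without a symbol (54 higher, 94 lower), immunoglobulin and T-cell receptor segments (2 and 37) and predicted genes (114 and 125) were counted but not named. Other members named to complete a count of 5 or fewer, and Pax5, Cd3e, Ptcra, Ctla4, Bcl11b, S100a8, S100a9, Mki67 and Ccnb1, were chosen after their values were seen.

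The fixed lists were B-lineage transcription factors, pre-B cell receptor and B-cell signalling, mature B-cell genes, plasma-cell genes, T-lineage transcription factors, T-cell receptor complex and T-cell surface genes, NK-cell, plasmacytoid dendritic-cell, neutrophil, monocyte, erythroid, basophil, and stem and progenitor genes, HOX genes and cofactors, chromatin regulators, proliferation, IL-7 and JAK-STAT, interferon, p53, stress and housekeeping genes.

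Alternatives set before the data were examined were other added constants (0.1 and 5), no filter and a filter at a mean of 5 FPKM, rescaling to the same total, to median ratios and by quantiles, array weights, robust variances, a replicate block, a threshold of 1 on the log2 difference, an adjusted p below 0.01, detection at 0.1 and 5 FPKM, and leaving out each library. For the detected genes, the block was an exact sign-flip test. Chosen after seeing the data were removal of the GC and length trend, libraries of a relative depth of at least 1.2 only, and leaving out GFP controls 7 and 8 together. Simulated data held 11694 genes with 200 changed. The procedure recovered 75% of those shifted by 0.5 and 97% of those shifted by 1 on the log2 scale. It called 0 of them in the wrong direction and 11 unchanged genes (0.0959%), and called the 1 shifted list of 26 members and 0 others. The simulated noise was independent between genes, and the 200 were drawn from the more abundant genes. The simulation therefore does not show how the list tests behave with correlated members, or the recovery of genes of low abundance. Some genes that the naming rule picked are not reported here, with no replacement, and stay in the counts and tests of their lists. Isoform values and raw reads were not analysed here.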

Results

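RNA abundance was compared between 8 libraries of mouse pro/pre-B cells transduced with a GFP control virus and 8 libraries transduced with a Hoxb5 virus, each made from 1000 sorted cells. Of 37980 listed genes, 11694 passed the filter on low values and were tested. Between 10822 and 11009 genes reached 1 FPKM in a library, and all values below are FPKM given as mean ± SD over n = 8 libraries per group unless another form is named. The labels do not say whether the replicates came from separate cultures or animals, so the p-values measure the spread between these libraries only, and that spread may be technical.

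Hoxb5, the homeobox gene carried by the virus, was listed at 2.57 to 4.73 FPKM in the 8 Hoxb5 libraries, with a mean of 3.71 ± 0.715. In the controls it was listed at 0 in 7 libraries and at 0.294 FPKM in GFP control 7. The difference was 2.17 on the log2(FPKM + 1) scale (SE 0.11, limma adjusted p = 3.8e-11), and the exact permutation p was 0.000155, the smallest that 8 against 8 libraries can give. The size of that difference depends on the added constant, from 0.79 with 5 to 4.98 with 0.1 FPKM. The values do not separate viral from chromosomal Hoxb5 RNA. The 3 housekeeping genes that moved did so in different directions. Actb, a cytoplasmic actin, fell from 1691 ± 152 to 1028 ± 117 FPKM. Gapdh, a glycolytic enzyme, rose from 584 ± 74.4 to 785 ± 42.4, and B2m, the light chain of MHC class I, rose from 3419 ± 226 to 4017 ± 251. Eef1a1, a translation elongation factor, was at 8148 ± 810.0 and 8237 ± 437 FPKM (adjusted p = 0.83), and the sign of its difference changes with the scaling.

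Several of the largest rises after Hoxb5 were in genes nearly silent in the controls. Arhgdig, a GDP-dissociation inhibitor, rose from 0.187 ± 0.392 to 40.5 ± 8.01 FPKM. Rgs11, a regulator of G-protein signalling, rose from 0.0357 ± 0.101 to 25.0 ± 3.17. Ifitm1, an interferon-inducible membrane protein, rose from 11.6 ± 2.31 to 216 ± 35.2, a ratio of means of 18.7. Kcng2, a potassium channel subunit, reached 15.0 ± 3.60 FPKM. Tmem132e rose from 3.22 ± 0.682 to 45.6 ± 2.73 and Tnnt2, cardiac troponin T, from 1.58 ± 0.643 to 22.7 ± 4.98. Ajuba, a LIM-domain protein, rose from 0.579 ± 0.287 to 11.7 ± 1.09 and Rab37, a small GTPase, from 2.44 ± 0.368 to 26.6 ± 2.28. Jam2, a junctional adhesion molecule, rose from 0.0370 ± 0.0763 to 7.10 ± 1.46. Klra17, a member of the killer-cell lectin-like receptor family, was listed at 0 in all 8 controls and at 6.65 ± 1.25 FPKM after Hoxb5, although reads of this family can be hard to assign to 1 member. The entries for the short RNAs Mir3082 (57.3 ± 104 to 85.1 ± 26.0 FPKM, adjusted p = 0.014) and mt-Tn (89.1 ± 105 to 210.1 ± 101, adjusted p = 0.033) also passed, with wide spread in the controls. The libraries were made from poly(A) RNA, and whether these values come from the short RNAs themselves was not tested. Mir3082 was at 0 in most controls but at 297 FPKM in GFP control 1, above every Hoxb5 library (at most 127). Its ratio of means was only 1.49. The call of mt-Tn was lost when 1 of GFP controls 1, 5 and 6 or 1 of Hoxb5 libraries 5, 6 and 7 was left out, with adjusted p up to 0.0672. It was also lost with no filter (adjusted p = 0.0699), with robust variances (0.0604) and in the libraries of a relative depth of at least 1.2 alone (0.131), where that of Mir3082 was lost too (0.0522).

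Arhgdig and Rgs11 lie next to each other on chromosome 17, where their exons share 138 bases, so some reads may count for either. Their neighbours were looked at after the values were seen, and 2 of them were higher in all 8 Hoxb5 libraries than in any control. Pdia2, a protein disulfide isomerase, rose from 0.123 to 2.57 ± 0.778 FPKM (adjusted p = 2.4e-07) and Fam234a from 2.25 to 5.69 ± 0.610 (adjusted p = 2.8e-08). Axin1, beyond Pdia2, rose from 23.2 to 27.2 FPKM (adjusted p = 0.013), and Luc7l, beyond Fam234a, was at 28.0 and 28.4 (adjusted p = 0.78).

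**Figure D1:**
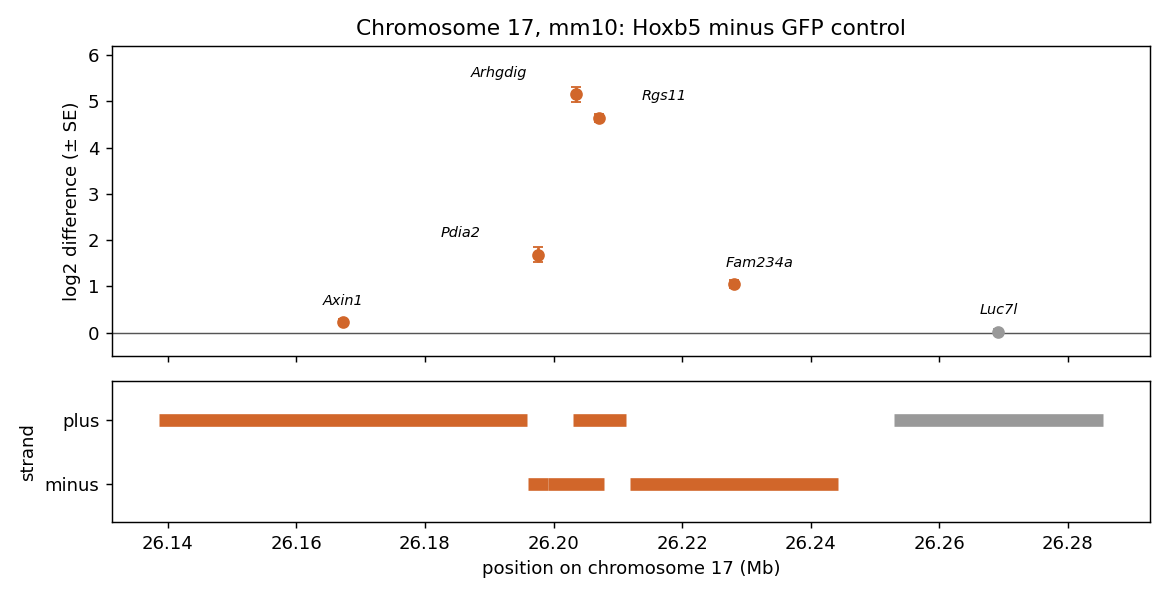
Log2 difference between Hoxb5 and GFP control libraries for genes along chromosome 17 around Arhgdig and Rgs11, on mm10 positions, with SE bars (n = 8 per group) and the extent and strand of each gene underneath. Pdia2, Arhgdig, Rgs11 and Fam234a form a run of 4 neighbours that are all higher by at least 1.

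Ly6d, a surface protein of B-lineage-biased lymphoid progenitors, fell from 4600.4 ± 439.6 to 514 ± 40.6 FPKM, a ratio of means of 0.112. Vpreb2, a part of the surrogate light chain, fell from 262 ± 29.9 to 47.2 ± 8.49, and Bst1, an ectoenzyme of early B cells and stroma, from 102 ± 15.2 to 15.5 ± 3.67. H2-DMb2, which helps load peptides on MHC class II, fell from 16.7 ± 2.25 to 1.63 ± 0.581. Malat1, a nuclear long noncoding RNA, fell from 166 ± 60.6 to 18.7 ± 3.83. GFP control 8, at 43.5 FPKM, was the control nearest the Hoxb5 libraries. Trf, transferrin, fell from 11.6 ± 1.69 to 1.38 ± 1.12 and Rnase6, a secreted ribonuclease, from 73.6 ± 5.50 to 13.3 ± 2.11. Uchl1, a ubiquitin hydrolase, fell from 94.0 ± 7.05 to 17.8 ± 2.52. Tmem59l (34.1 ± 5.81 to 4.65 ± 1.57), Tmem71 (16.2 ± 1.502 to 2.15 ± 0.442), Rpl3l, a paralog of a ribosomal protein (27.8 ± 4.10 to 4.93 ± 2.29), and Pcp4l1 (6.84 ± 1.54 to 0.509 ± 0.203) fell as well. All 24 genes of these 2 groups lay on the same side of the control median in 8 of 8 Hoxb5 libraries.

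**Figure D2:**
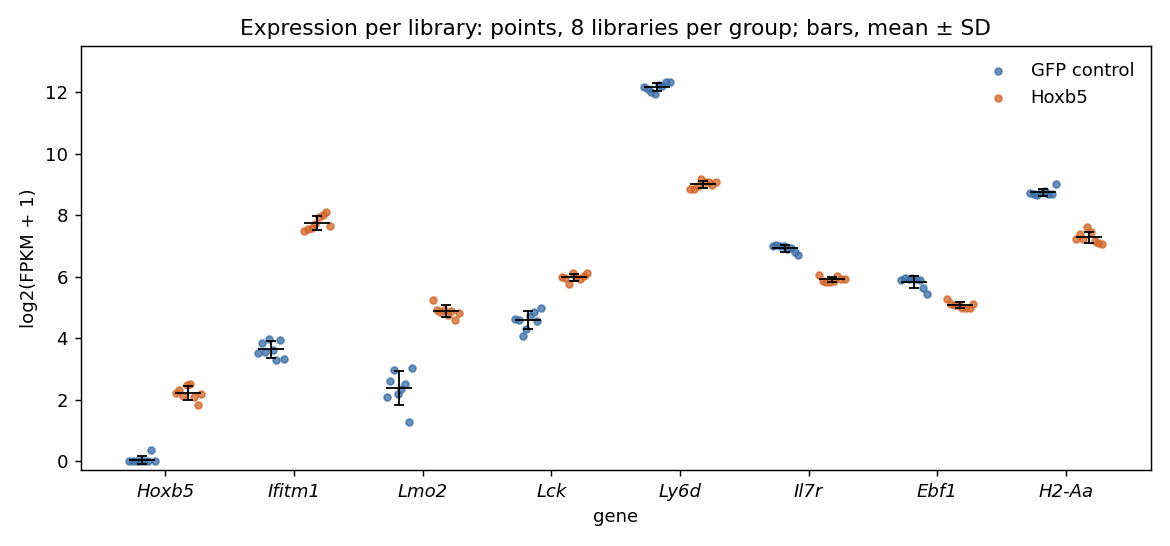
Abundance of Hoxb5, Ifitm1, Lmo2, Lck, Ly6d, Il7r, Ebf1 and H2-Aa as log2(FPKM + 1), with GFP controls in blue and Hoxb5 libraries in orange. Each point is 1 of the 16 libraries, and bars give mean ± SD (n = 8).

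Across all tested genes, 2357 were higher and 2329 lower after Hoxb5 at a limma adjusted p below 0.05, and 7008 were not called. The balance depends on the scaling, with 1951 higher and 2403 lower after rescaling to the same total. Most differences were small: 203 of the higher and 288 of the lower genes differed by at least 1 on the log2 scale. Libraries correlated at 0.964 to 0.976 within controls, 0.970 to 0.982 within Hoxb5 libraries and 0.945 to 0.961 between them. The Hoxb5 libraries had fewer genes at 1 FPKM or more (10858.9 ± 30.5 against 10948.4 ± 54.7, exact permutation p = 0.00342), although the difference at 0.1 FPKM or more was 91.1 genes the other way (exact permutation p = 0.258). They also differed in relative depth, 1.45 ± 0.187 against 1.13 ± 0.217 (exact permutation p = 0.00963), and in mitochondrial share, 5.97 ± 0.513% against 6.79 ± 0.853% (exact permutation p = 0.0235). With only the libraries of a relative depth of at least 1.2, the counts were 1552 and 1399. These were 4 controls at 1.23 to 1.41, GFP controls 7 and 8 among them, and 7 Hoxb5 libraries at 1.44 to 1.61, so every Hoxb5 library was still deeper than every control. An addition of 1 FPKM before the log understates differences of genes near or below that level.

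B-lineage genes mostly fell. Of 15 transcription factors of the lineage, 12 fell, 1 rose and 2 were not called, with the same 12 and 1 adjusted over the list alone (camera adjusted p = 1.2e-05, adjusted p = 0.035 with an estimated correlation). The latter was 0.361 after rescaling to the same total, 0.109 by quantiles and 0.0533 in the libraries of a relative depth of at least 1.2. By median ratios it was 0.0402. Irf4, which acts in pre-B and plasma cell differentiation, fell from 101 ± 4.54 to 60.2 ± 3.64 FPKM, and Bach2, a repressor of plasma cell fate, from 72.9 ± 9.33 to 39.5 ± 2.72. Ebf1, an early specification factor, fell from 56.0 ± 6.95 to 32.7 ± 2.32. Foxo1, which activates the recombinase genes, fell from 79.1 ± 2.98 to 58.0 ± 1.43, and Pax5, the B-cell commitment factor, fell by 1.02 on the log2 scale. Irf8, shared with myeloid cells, was the member that rose. GFP control 8 had the lowest control mean of this list, 5.94 against 6.199 to 6.32 in the other controls, on the log2(FPKM + 1) scale.

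Among 20 genes of the pre-B cell receptor and B-cell signalling, 14 fell, 4 rose and 2 were not called, or 15 and 4 adjusted over the list alone (camera adjusted p = 3.8e-04, adjusted p = 0.014 with an estimated correlation, but 0.262 after rescaling to the same total and 0.0544 by quantiles). By median ratios the camera adjusted p with an estimated correlation was 0.00738. Il7r, the receptor chain for IL-7, fell from 120.0 ± 9.08 to 59.1 ± 3.46 FPKM. Cd24a, a surface glycoprotein of developing lymphocytes, was among the 4 that rose, from 1392 ± 115 to 4375 ± 223, with Cd22, Cd72 and Plcg2. Of 14 tested mature B-cell genes, 9 fell and 5 rose, the same adjusted over the list alone (camera adjusted p = 0.0097, adjusted p = 0.16 with an estimated correlation). The class II genes H2-Eb1 (157 ± 10.4 to 42.0 ± 7.14) and H2-Aa (429 ± 35.8 to 155 ± 21.6) and the chemokine receptor Ccr7 (47.7 ± 4.38 to 19.3 ± 2.26) fell. Of 6 tested plasma-cell genes, 3 rose, 0 fell and 3 were not called, with 3 adjusted over the list alone (camera adjusted p = 0.0074, adjusted p = 0.038 with an estimated correlation, but 0.0762 after rescaling to the same total, 0.0707 by quantiles and 0.0805 in the libraries of a relative depth of at least 1.2). By median ratios the camera adjusted p of this list with an estimated correlation was 0.0458. The 3 that rose were Sdc1, the surface proteoglycan CD138 (6.83 ± 0.851 to 26.8 ± 3.37), Mzb1, an endoplasmic reticulum cochaperone (406 ± 37.8 to 735 ± 39.7), and Prdm1, the plasma-cell regulator Blimp-1 (0.332 ± 0.164 to 1.51 ± 0.185).

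Neither list of T-lineage genes passed the camera test, and members moved both ways. Of 15 T-lineage transcription factors, 8 could be tested: 2 rose, 4 fell and 2 were not called, the same adjusted over the list alone (camera adjusted p = 0.43). Dtx1, a Notch pathway regulator, rose from 21.2 ± 2.84 to 32.6 ± 2.59 FPKM. Gfi1, a repressor (14.3 ± 2.34 to 7.85 ± 1.15), Hes1, a Notch target (7.10 ± 1.43 to 3.50 ± 1.35), and Runx1 (14.7 ± 1.23 to 11.2 ± 1.74) fell. The call of Runx1 was lost in the libraries of a relative depth of at least 1.2 (adjusted p = 0.0565), where 1 of the 8 transcription factors rose and 2 fell. Of 25 genes of the T-cell receptor complex and T-cell surface, 9 could be tested: 5 rose, 3 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.29). Lck, a kinase of T-cell receptor signalling also present in early B cells, rose from 23.4 ± 4.78 to 62.4 ± 4.89, and Il2ra, an IL-2 receptor chain, from 29.2 ± 2.32 to 48.6 ± 2.63. Thy1, a surface glycoprotein, rose from 4.78 ± 1.44 to 10.5 ± 1.22. Cd2, an adhesion molecule, fell from 169 ± 16.8 to 79.9 ± 10.3. Cd3e, Ptcra, Ctla4 and Bcl11b were listed at 0 in all 16 libraries. The mean of the T-cell surface list, 0.18, changed sign to -0.05 with an addition of 0.1 FPKM. With the filter at a mean of 5 FPKM it was 0.49 and the list passed (camera adjusted p = 0.0362). In the libraries of a relative depth of at least 1.2, 8 of its genes could be tested, of which 3 rose and 1 fell.

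Most markers of other blood cells were low in both groups. Of 12 NK-cell genes only Klrd1, an NK receptor chain, could be tested, at 0.948 ± 0.663 FPKM in controls and 0.513 ± 0.678 after Hoxb5 (adjusted p = 0.20). Another 6 were listed at 0 in every library, and the count adjusted over the list alone was 0. Of 15 neutrophil and granule genes 0 could be tested and 9, among them S100a8 and S100a9, were listed at 0 in every library. Of 8 basophil and mast-cell genes 0 could be tested and 5 were listed at 0. Of 16 erythroid and megakaryocyte genes, 2 were tested: Car2, a carbonic anhydrase also made outside red cells, fell from 28.0 ± 2.26 to 5.96 ± 0.959 and Klf1 was not called, with 1 lower adjusted over the list alone. Of 6 tested plasmacytoid dendritic-cell genes, 3 rose, 2 fell and 1 was not called, the same adjusted over the list alone (camera adjusted p = 0.75). Siglech, a surface lectin (0.194 ± 0.128 to 1.45 ± 1.05), and Cox6a2 (8.26 ± 2.61 to 12.6 ± 2.03) rose, and Tcf4 (19.5 ± 3.49 to 13.3 ± 1.23) and Ly6d fell. The mean of that list was -0.23 and its median 0.37, with Ly6d the largest single difference. Of 8 tested monocyte and macrophage genes, 2 rose, 3 fell and 3 were not called, the same adjusted over the list alone (camera adjusted p = 0.71). Csf1r, the M-CSF receptor, rose from 0.659 ± 0.267 to 5.67 ± 0.910, and Ly6c2 (5.86 ± 1.11 to 0.687 ± 1.09), Ms4a6c (1.54 ± 0.667 to 0.298 ± 0.223) and lysozyme Lyz2 (4.61 ± 1.73 to 1.66 ± 0.873) fell. The mean of the monocyte list was -0.19 and its median -0.03, while the fry test pointed up (adjusted p = 0.30).

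Of 10 tested stem and progenitor genes, 4 rose, 1 fell and 5 were not called, the same adjusted over the list alone (camera adjusted p = 0.079). The list passed camera with the filter at a mean of 5 FPKM (0.85, adjusted p = 0.0102) and in the libraries of a relative depth of at least 1.2 (0.59, adjusted p = 0.0179), the latter with adjusted p = 0.151 with an estimated correlation. Lmo2, a bridging factor of progenitor transcription complexes, rose from 4.50 ± 1.88 to 28.5 ± 4.001 FPKM, and Ly6a, the stem-cell antigen Sca-1, from 5.83 ± 1.87 to 16.6 ± 2.77. Hhex, a homeobox gene of progenitors, rose from 10.8 ± 3.45 to 23.5 ± 3.04, with Gfi1b the last of the 4. Erg, an ETS factor, fell from 6.55 ± 1.24 to 2.60 ± 0.574. Of 8 tested HOX genes and cofactors other than Hoxb5, only the cofactor Pknox1 rose (18.0 ± 0.631 to 22.1 ± 1.81), 0 fell and 7 were not called, the same adjusted over the list alone (camera adjusted p = 0.43), and 10 of the 28 members were listed at 0 in every library.

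Of 26 proliferation genes, 16 rose, 2 fell and 8 were not called, or 17 and 3 adjusted over the list alone (camera adjusted p = 1.7e-04, adjusted p = 0.16 with an estimated correlation). Those with the smallest p were DNA replication genes: the helicase subunits Mcm2 (40.0 ± 3.17 to 84.6 ± 4.09 FPKM) and Mcm6 (71.4 ± 3.99 to 118 ± 6.59), the polymerase clamp Pcna (362 ± 19.4 to 571 ± 48.5) and thymidylate synthase Tyms (91.1 ± 7.93 to 142 ± 8.79). Mki67 and the mitotic cyclin Ccnb1 were the 2 that fell. Of 54 tested chromatin regulators, 27 fell, 6 rose and 21 were not called, or 28 and 7 adjusted over the list alone (camera adjusted p = 0.0026, adjusted p = 0.18 with an estimated correlation). Smarca4, an ATPase of SWI/SNF (350.4 ± 16.98 to 215 ± 6.50), and Brd2, a bromodomain protein (97.1 ± 13.98 to 42.1 ± 8.96), fell. Ezh1, a histone methyltransferase (14.2 ± 1.11 to 25.0 ± 1.37), and Dnmt1, the maintenance DNA methyltransferase (38.5 ± 4.29 to 58.7 ± 2.10), rose. In the libraries of a relative depth of at least 1.2, 14 of the chromatin regulators fell and 4 rose. With the GC and length trend removed, 20 fell and 6 rose. GFP control 8 had the lowest control mean of this list, 3.91 against a Hoxb5 mean of 3.90, and without GFP controls 7 and 8 the list passed with an estimated correlation (adjusted p = 0.00628).

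Stress and immediate-early genes fell: 11 of 15 were lower, 0 higher and 4 not called, with 11 adjusted over the list alone (camera adjusted p = 3.2e-06, adjusted p = 0.0012 with an estimated correlation). This list was fixed as a check of sample quality. An effect of Hoxb5 on it and a difference in how the groups were handled cannot be told apart. The AP-1 genes Fos (60.0 ± 4.16 to 18.0 ± 2.92 FPKM), Fosb (12.3 ± 1.43 to 3.52 ± 0.567) and Jun (20.8 ± 2.74 to 10.8 ± 1.64) and the chaperone Hsp90aa1 (121 ± 13.4 to 78.5 ± 6.10) fell. Of 15 tested p53 and apoptosis genes, 7 fell, 2 rose and 6 were not called, the same adjusted over the list alone (camera adjusted p = 0.026, adjusted p = 0.062 with an estimated correlation). Cdkn1a, a cell-cycle inhibitor (32.7 ± 1.85 to 18.4 ± 1.99), Trp53inp1 (35.2 ± 4.89 to 18.5 ± 1.71), Mdm2 (34.2 ± 1.39 to 24.3 ± 1.26) and Gadd45a (19.7 ± 3.64 to 11.6 ± 2.52) fell. The death receptor gene Fas and Bcl2l11 rose. Of 15 tested IL-7 and JAK-STAT response genes, 8 fell, 3 rose and 4 were not called, or 9 and 3 adjusted over the list alone (camera adjusted p = 0.098, adjusted p = 0.27 with an estimated correlation). With the GC and length trend removed these were 0.0411 and 0.217. The kinase genes Pim2 (77.2 ± 4.28 to 25.5 ± 2.39) and Pim1 (13.2 ± 3.14 to 4.81 ± 0.830) and cyclin Ccnd2 (46.7 ± 4.12 to 16.6 ± 2.41) fell. Socs2, a feedback inhibitor, rose from 55.0 ± 4.10 to 131 ± 7.93.

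Of 15 tested type I interferon response genes, 2 rose, 2 fell and 11 were not called, the same adjusted over the list alone (camera adjusted p = 0.97). The antiviral genes Oas1a (12.5 ± 1.63 to 15.8 ± 1.82 FPKM) and Oas2 (6.32 ± 1.37 to 8.41 ± 0.548) rose. Ddx58, the RNA sensor RIG-I (15.9 ± 2.59 to 11.2 ± 1.71), and Isg20 (16.6 ± 2.45 to 12.9 ± 2.92) fell. The calls of Oas1a, Oas2 and Isg20 were lost in the libraries of a relative depth of at least 1.2 (adjusted p = 0.144, 0.121 and 0.188). Of the 4 housekeeping genes, 2 rose, 1 fell and 1 was not called, the same adjusted over the list alone, with a mean of -0.01, a median of 0.13 and a camera test pointing up (adjusted p = 0.71). In all, 8 of the 17 testable lists passed, and 4 of them, the B-lineage transcription factors, the pre-B cell receptor, plasma-cell and stress lists, did so with an estimated correlation. Of those 4, only the stress list, fixed as a check of sample quality, also did after rescaling to the same total (adjusted p = 0.0371 with an estimated correlation) and by quantiles (0.0011). By median ratios all 4 passed with an estimated correlation (0.0402, 0.00738, 0.0458 and 0.00124). With the GC and length trend removed all 4 passed (0.00449, 0.00164, 0.0461 and 0.000389), as did the mature B-cell (0.0449), proliferation (0.0461) and p53 lists (0.0449). By exact permutation of the mean of each list over libraries, 15 of the 17 lists had an adjusted p below 0.05. For 9 of them p was the smallest the 16 libraries allow, 0.000155. This permutation does not set a list against other genes, and 4686 of the 11694 tested genes were called. A list can thus pass it without standing out, as the monocyte (adjusted p = 0.0149) and HOX lists (0.0166) did, which camera did not call.

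**Figure D3:**
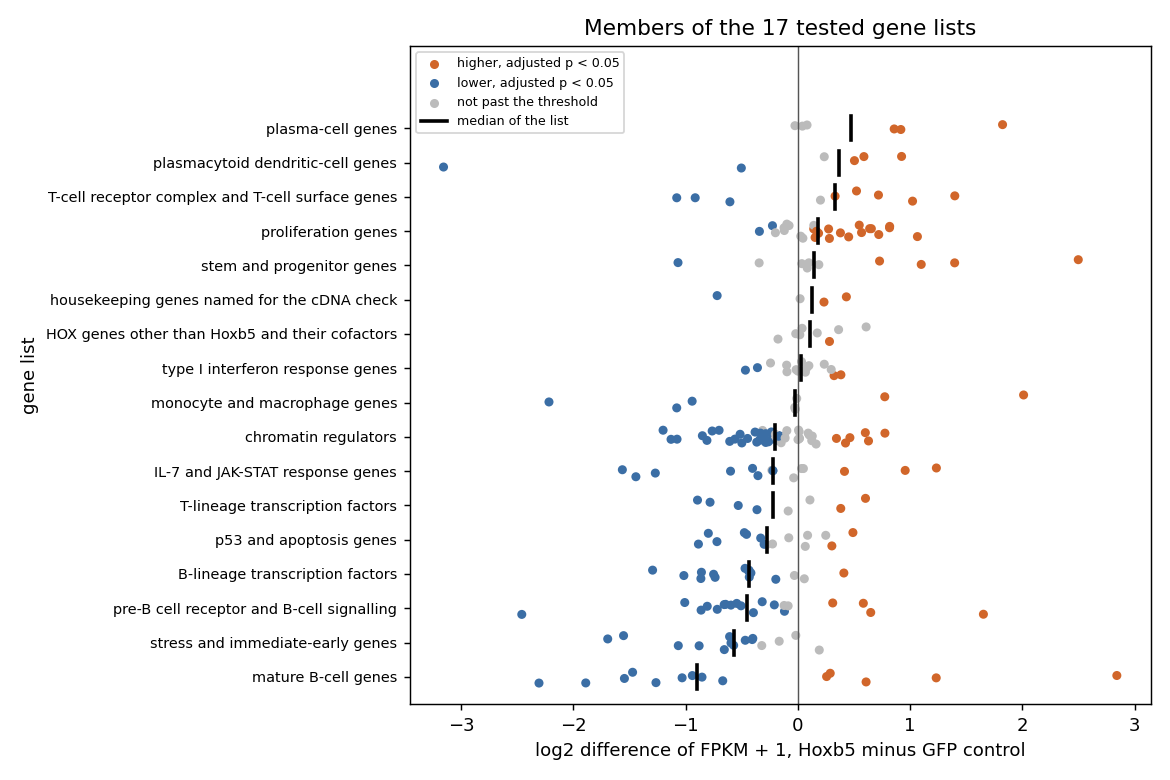
Log2 difference between Hoxb5 and GFP control libraries for each tested member of the 17 gene lists tested, higher genes in orange, lower in blue and those not called in grey. The black bar is the median of the list, and 11 of 15 stress and immediate-early genes and 12 of 15 B-lineage transcription factors are lower.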

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

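All tests weighed here were chosen after the results were seen. Of 220 groups of 8 values checked for a library far from the rest, 32 were picked out. The rule would pick about 1 in 20, or 11, if the values were independent and normally distributed. Genes found in only 1 control, such as Hoxb5, Rgs11 and Kcng2, are picked out whatever their level. Genes and the lists that hold them, such as Mcm6 and the proliferation list, were both counted. The 11 is therefore not a valid chance level, and the 32 values picked out are only described.

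GFP control 7 carried 8 of these values. Hoxb5 was at 0.294 FPKM there and at 0 in the other controls. Arhgdig was at 1.09 FPKM (at most 0.399 in the others), Jam2 at 0.211 (at most 0.0849), and Hes1 at 10.3 (5.69 to 7.47). Mcm6 was lowest of the controls at 62.1 (71.1 to 74.4), as were the proliferation list at a mean of 6.22 (6.34 to 6.42) and the interferon list at 2.95 (3.05 to 3.13), and ribosomal-protein genes held 26.1% of the FPKM total (22.9 to 23.6%).

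GFP control 8 also carried 8. Gapdh was highest of the controls at 749 FPKM (504 to 613), H2-Aa at 513 (405 to 439), Mzb1 at 488 (376 to 425) and Rgs11 at 0.286 (0 in the others), while Fos was lowest at 51.2 (58.4 to 64.2). The B-lineage transcription factor list was lowest at a mean of 5.94 (6.199 to 6.32), the chromatin regulators at 3.91 (4.07 to 4.197), and 10825 genes reached 1 FPKM (10927 to 11009 in the others).

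In GFP control 1, Mir3082 was highest at 297 FPKM (0 to 93.1) and Trf at 15.1 (9.30 to 11.9). In GFP control 3, Kcng2 was at 0.959 FPKM (0 in the others), Pcp4l1 at 10.3 (5.45 to 7.34) and Cd24a at 1649 (1275 to 1416), and the 10 most abundant genes held 12.5% of the total (10.9 to 11.4%). In Hoxb5 1, Rab37 was lowest of its group at 21.7 FPKM (25.7 to 28.8), and Ebf1 at 37.4 (30.2 to 33.6), Lmo2 at 37.0 (22.8 to 29.1) and Mcm6 at 134 (113 to 118) were highest. Runx1 was highest in Hoxb5 2 at 15.0 FPKM (9.57 to 11.9) and Thy1 lowest there at 7.70 (10.1 to 11.6). Lyz2 was highest in Hoxb5 6 at 3.57 FPKM (0.582 to 1.87), while Socs2 was lowest in Hoxb5 7 at 113 (128 to 139). In Hoxb5 8, Ccnd2 was highest at 21.8 FPKM (13.98 to 17.3) and the relative depth lowest at 1.00 (1.44 to 1.61).

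Hoxb5 signal in GFP control 7 could come from RNA of a Hoxb5 library carried into it, or from exchanged labels. Exchanged labels are argued against by the position of the library, -21.1 on the first component, where controls lay between -30.3 and -17.4 and Hoxb5 libraries between 20.5 and 29.8. For carry-over, 5 genes near 0 in most controls and at 5 FPKM or more after Hoxb5 (Arhgdig, Jam2, Kcng2, Klra17 and Rgs11) together reached 1.38% of their Hoxb5 level in GFP control 7, against 0 to 1.11% in the other controls. Hoxb5 itself reached 7.93%, and at that share Rgs11 would be at 1.98 FPKM, and it was at 0, and Arhgdig at 3.21, and it was at 1.09. Carry-over and a low signal of Hoxb5 in that library cannot be told apart by this test.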

How the results depend on the processing

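Removing the GC and length trend, keeping a relative depth of at least 1.2 and leaving out GFP controls 7 and 8 were chosen after the data were seen. No gene called in both changed direction under any alternative, but not all calls were kept. The log2 difference followed GC content (Spearman rho 0.252) and log2 transcript length (-0.183) over the 11129 genes with a value. With that trend removed, 2174 genes were higher and 2279 lower. Of these, 1868 and 1930 were also called with the values as deposited, where the counts were 2357 and 2329. Leaving out 1 library gave 2144 to 2470 higher and 2101 to 2418 lower genes, 8 lists each time, and a Hoxb5 difference of 2.13 to 2.23. At a difference of at least 1 there were 203 and 288 genes, and with the 4 controls and 7 Hoxb5 libraries of a relative depth of at least 1.2 there were 1552 and 1399, where the first asks for a larger difference and the second has fewer samples and keeps the Hoxb5 libraries deeper. The number of lists called was 4 with an estimated correlation and 14 with fry. The mature B-cell list, at -0.48, was not called with an estimated correlation (adjusted p = 0.16), and the T-lineage transcription factors (-0.20, adjusted p = 0.0185) and T-cell surface genes (0.18, adjusted p = 0.000667) were called with fry. The T-cell surface list was at 0.49 (camera adjusted p = 0.0362) with the filter at a mean of 5 FPKM, where fewer genes are tested, and at -0.0528 (adjusted p = 0.296) with an addition of 0.1. The difference in genes detected was 91.1 at 0.1 FPKM (exact permutation p = 0.258), and -107 to -80.8 at 1 FPKM on leaving out 1 library. Hoxb5 has no value with a mean FPKM of at least 5.

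Besides the T-cell surface list and the genes detected, the reversals were in 3 results near 0, and the cause was not tested for any of these 5. Eef1a1 was at -0.0186 rescaled to the same total, -0.0795 by quantiles, -0.000248 without GFP control 7, -0.00103 without Hoxb5 4, -0.0252 with the trend removed and -0.0446 at a relative depth of at least 1.2, and leaving out 1 library gave at most 0.0576. The interferon list was at -0.0222 with no filter, -0.0163 rescaled to the same total, -0.0033 without GFP control 7, -0.0233 with the trend removed and -0.00993 without GFP controls 7 and 8, and leaving out 1 library gave at most 0.0293. The housekeeping list was at 0.00175 with array weights, 0.000134 without GFP control 3 and 0.00554 without Hoxb5 1, and leaving out 1 library gave at least -0.0216. Of the named-gene values, 2462 kept their call and direction, 14 were weaker in 6 genes and 6 reversed in 1, and of the list values 502 kept theirs, 10 were stronger, 4 weaker and 9 reversed. As a block, the replicate number gave 2349 higher and 2243 lower genes. Correlations of same-number libraries ran from -0.07 to 0.16 with 1 above 0.1, and 2 of 8 libraries correlated best with their own number, so the pairing is not used. Shallower libraries limit genes near 1 FPKM most.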

Other observations

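The gene groups in this part were chosen after the values were seen, as were all tests weighed below, and they share members with the lists fixed earlier. The adjusted p-values of these groups therefore describe them only and do not control the rate of false calls. All 14 tested genes of the pro-B and large pre-B stage fell after Hoxb5 (camera adjusted p = 1.4e-13, adjusted p = 4.5e-05 with an estimated correlation). Among them the aminopeptidase gene Enpep fell from 30.5 ± 5.61 to 6.05 ± 1.63 FPKM (SD, n = 8 libraries per group). Of 16 later-stage B-cell genes, 11 fell and 5 rose (adjusted p = 3.6e-04, adjusted p = 0.033 with an estimated correlation), among them Tnfrsf13c, Cd40, Cd22 and Cd83. MHC class II genes fell, 9 of 10 with H2-Oa not called (adjusted p = 5.4e-09, adjusted p = 0.017 with an estimated correlation), while of 12 MHC class I genes 6 rose, 2 fell and 4 were not called (adjusted p = 0.026, adjusted p = 0.24 with an estimated correlation, and 0.134 after quantile scaling or 0.153 with the GC and length trend removed).

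Of 27 replication licensing and S-phase genes, 24 rose, E2f2 fell and 2 were not called (adjusted p = 1.1e-11, adjusted p = 0.0036 with an estimated correlation), while 22 mitosis genes were split into 5 higher, 5 lower and 12 not called (adjusted p = 0.45), or 1 and 5 after rescaling to the same total, 1 and 6 by quantiles and 3 and 5 by median ratios. Glycolysis genes rose, 11 of 15 with 0 lower (adjusted p = 3.0e-07, adjusted p = 0.020 with an estimated correlation). The enzyme genes Aldoa (185 ± 11.6 to 428 ± 26.1 FPKM, SD, n = 8) and Tpi1 (85.2 ± 10.3 to 178 ± 11.9) were among them. Genes of the ATF4 amino-acid response fell in 9 of 15 with 2 higher (adjusted p = 0.0026, adjusted p = 0.020 with an estimated correlation). The asparagine synthetase gene Asns fell from 9.31 ± 1.44 to 2.001 ± 0.813 FPKM, and Psat1 and Psph were the 2 that rose. Actin and SRF target genes fell in 8 of 15 with 1 higher (adjusted p = 0.016, adjusted p = 0.030 with an estimated correlation), or 3 with 0 higher in the libraries of a relative depth of at least 1.2. Cholesterol synthesis genes were 3 higher, 5 lower and 10 not called (adjusted p = 0.19), and of 4 nuclear-retained long RNAs 2 rose and 1 fell (adjusted p = 0.73), with a mean of -0.54, a median of 0.12 and a camera test pointing up. After rescaling to the same total, only the pro-B and large pre-B (adjusted p = 0.00605) and MHC class II lists (0.0309) were still called with an estimated correlation. The replication (0.101), glycolysis (0.101), later-stage (0.149), ATF4 (0.203) and actin (0.285) lists were not. By median ratios these lists were called with an estimated correlation (0.0011, 0.0159, 0.0332, 0.0195 and 0.0273). With an estimated correlation, the actin list was not called by quantiles (0.118) either, and in the libraries of a relative depth of at least 1.2 neither it (0.0509) nor the later-stage list (0.0512) was.

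The run of 4 higher neighbours on chromosome 17 could come from shared reads, coincidence, or a vector inserted nearby in a clone that expanded. Arhgdig and Rgs11 share 138 annotated exon bases, 8.81% of Arhgdig and 3.28% of Rgs11. Fam234a, whose annotated exons overlap no other gene of the group, differed by 1.05 on the log2 scale. That argues against reads of shared annotated exons alone. Reads outside annotated exons, such as those running past the end of a gene, were not checked. With overlapping genes counted as 1, the run was 3 long and 700 of 10000 random orders held one as long (permutation p = 0.07), against 12 with each gene counted alone (permutation p = 0.0013), so coincidence stays open. Arhgdig was above every control in 8 of 8 Hoxb5 libraries, so coincidence, an insertion in a clone present in all 8 and an effect of Hoxb5 on the locus cannot be told apart. The last of these was not tested.

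Lower B-lineage lists could come from fewer B-lineage cells, from a shift along the B-cell stages, or from the trend with GC content and length. The highest mean among neutrophil, basophil, NK and erythroid markers in the Hoxb5 libraries was 5.96 FPKM, of Car2. It was below the bound of 50 FPKM set for another lineage, which argues against large numbers of those cells. The cells had been sorted as pro/pre-B cells, so low markers were likely in any case. T-cell, monocyte and plasmacytoid dendritic-cell genes, which moved both ways, were not part of this check. It does not decide whether B-lineage cells were fewer. Of the mature B-cell genes, 9 fell and 5 rose (exact sign test p = 0.424). A shift along the stages and other reasons cannot be told apart by this test, since members moved both ways. It also takes the members as independent, although the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 were among those that fell. With the trend removed the B-lineage transcription factors were at -0.46 against -0.50, which argues against GC content and length as the main source. Hoxb5 and any other difference in how the 2 groups were handled stay open, since each group has 1 virus.

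Over 100 drawn splits of the 16 libraries into 8 and 8, only the real grouping reached its own counts, 1 of 100 in each case. It gave 2357 higher genes, 2329 lower genes and 8 lists, against at most 1128, 1128 and 6 in any other drawn split. That argues against a chance division of the libraries, although only 100 of the 6435 possible splits were drawn. The splits do not weigh a difference in depth or handling that runs with the groups.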
